A study of Gallus gallus with 12 samples.

How the data were processed

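Spleen RNA of young chickens was compared on 12 two-colour spotted arrays. Per the labels, 183 chicks entered isolators at 13 days of age, 160 were challenged at 21 days with infectious bursal disease virus (IBDV), a birnavirus that destroys B cells of the bursa of Fabricius, and 23 were kept unchallenged in a separate isolator. Spleens were taken at 24 days, 3 days after challenge. The submitters called a challenged bird resistant (R) when its bursa held little virus and susceptible (S) when it held much, and unchallenged birds were the controls (C). Each group was divided into 4 RNA pools of 2 birds, except that pools R1 and S1 were single birds, so that 22 birds were used (7 R, 7 S and 8 C). Per the labels' protocols, total RNA was amplified with an oligo(dT) primer, copied into aminoallyl cDNA and coupled to Cy3 or Cy5.

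The authors' deposited values are 1 log2-type ratio per feature and array: 15769 features on 12 arrays, with no missing value and with every array's median near 0. The log base, background correction and normalization are not given in the sources used here. Base 2 was assumed for the folds, which are therefore given as folds if the base is 2, and no test depends on the base. Intensities were not analysed here, so a dim feature could not be told from a bright one, and the number of arrays limits the precision. Tested features were named by clone and well, apart from PEN_c-rel, PEN_mtd and PEN_TF-10, which were called in no comparison. None of these names matched the gene table of the reference, so that no feature was given a gene name. For this reason the planned pathway and cell type lists, the averaging of features of 1 gene, and the use of sex-linked genes to set the sign of the ratios or to check the sex of the pools were not run. The 160 features that bear the names of control spots (Cab, NAC1, PRKase, RUBISCO and ChickenGenomic) were left out, and 15609 features were tested.

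Each of the 4 sets held 3 arrays (R against S, R against C and S against C) that measured the same 3 pools in a loop in which each pool carried each dye once. The sum round a loop should be near 0, apart from noise and any dye effect, when the signs of the 3 arrays are read correctly. In 4 of 4 sets the sum was narrowest with every value read as the first-named over the second-named pool, or with all 12 values turned together. Read as Cy5 over Cy3, the sums were wider in every set and limma called 0 features in each comparison, with 700 to 846 at unadjusted p under 0.05. The loops cannot tell the first-named reading from its mirror image. The likely reading, first-named over second-named, was taken from the way the array titles name the pools and from the first-named pool being channel 1. If the ratios run the other way, every "higher" becomes "lower" and no count changes.

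For every set and feature, the 3 arrays were solved by least squares for the 3 pools, which cancels the dye effect. The pool values were fitted in limma 3.58.1 (R 4.3.3) with set and group as terms, so that the pool was the replicate (n = 4 per group), with 6 residual and 3.32 prior degrees of freedom. The set is a block because ratios exist only within sets and because the arrays of a set share their pools. Comparisons were R against C, S against C, R against S and the mean of R and S against C (infected against C). P-values are two-sided and were adjusted by the Benjamini-Hochberg method over 15609 features, with adjusted p under 0.05 as the threshold. Errors are SDs over the 4 set values. These choices, the groups, the rule for named features in outline and most of the alternatives below were made before the data were examined.

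The rule for naming, where no gene name can be given, was at most 2 features that rose and 2 that fell: those with the largest change in S against C among called features with the same sign in 4 of 4 sets. The 2 features with the smallest p in R against S are given as values. These 2 were an addition to the rule, which also had not fixed S against C as the comparison to use. The fit was tested on simulated arrays with the spread of the 15609 real features. In S against C it recovered 56% of 100 changes of 0.5 log units and 99% of 100 changes of 1 log unit, with 9 false among 164 calls. The simulated noise was Gaussian, independent between features and without plate offsets, so that these rates need not hold for the real arrays.

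Alternatives were median centring and limma's scale normalization of the arrays, no set block, the direct arrays alone, the spread of 1 comparison alone, limma quality weights, the share of males in a pool as a covariate, each set left out, and an adjusted p under 0.10. Quality weights were estimated per set, since pool values within a set are only relative. Filters on missing values change nothing here, as no value is missing. The sex labels of 2 pools (S3 and C3) disagree between arrays, and the covariate was fitted with both pools as females and again as males. Chosen after seeing the data were the centring of each of 69 source plates with at least 50 features, the removal of sets with an absolute loop sum over 1, robust eBayes, the tests in left-out sets, the covariance between sets and the tests of clone families.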

Results

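The data were 12 two-colour arrays of spleen RNA, 3 from each of 4 sets of pools from IBDV-resistant (R), IBDV-susceptible (S) and unchallenged (C) chickens, sampled 3 days after challenge. Each array gave a log ratio for 15609 tested features, known here by clone and well names apart from 3 whose names begin with PEN. Signs are given with the first-named group over the second. This reading is likely rather than settled, and its mirror image would exchange higher and lower throughout. Array medians lay between -0.02 and 0.02, and single-array SDs between 0.247 and 0.583. The technical SD of an array was taken from the median absolute deviation, scaled to an SD, of the sum round each loop of 3 arrays. It was 0.264 in set 1, 0.150 in set 2, 0.187 in set 3 and 0.161 in set 4. The tails of the sum count little in it. Over sets 1 to 4 the plain SD of the sum was 0.833, 0.402, 0.525 and 0.426. The scaled deviation was 0.457, 0.260, 0.324 and 0.279. A dye effect would raise the technical SD, since it adds up over the 3 arrays in that sum. The median feature's SD between sets was 0.190 for R minus C, 0.177 for S minus C and 0.175 for R minus S, against a technical SD of 0.160 for a set value. The dye effect cancels in set values but would raise that technical SD, in which the tails count little too. No feature showed a dye effect past adjusted p 0.05 in limma (1306 at unadjusted p under 0.05, where 780.45 would arise with no effect).

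The comparison of S with C asked what the spleen of susceptible birds expressed differently after challenge. In susceptible spleens 82 features were higher and 82 lower than in unchallenged spleens. Changes were mostly small: the median size among the 164 features was 0.54 log units and the range 0.33 to 1.78. The largest rises were C0004117_P2, 1.78 ± 0.73 (SD, n = 4; 3.44-fold if the log base is 2; adjusted p = 0.0344), and C0004112_O12, 1.75 ± 0.35 (SD, n = 4; 3.36-fold on base 2; adjusted p = 0.00834). The largest falls were Pat_4A3, -1.26 ± 0.45 (SD, n = 4; 2.40-fold lower on base 2; adjusted p = 0.0416), and Pat_4A1, -1.16 ± 0.56 (SD, n = 4; 2.24-fold lower on base 2; adjusted p = 0.0464), which have nearby wells on 1 plate. Of all tested features, 27.6% had the same sign in 4 of 4 sets, where 12.5% would by chance. At unadjusted p under 0.05 there were 2827 features, where 780.45 would arise with no effect.

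The count of 164 rested on all 4 sets: limma called 0 without set 1, 0 without set 2, 3 without set 3 and 0 without set 4, with 1800 to 2732 features at unadjusted p under 0.05. The named features kept their signs (C0004112_O12 between 1.64 and 1.89 over all alternatives). The count fell to 1 or 0 with the share of males as a covariate, to 1 with the spread of this comparison alone and to 0 with the direct arrays alone. It rose to 288 with scale normalization and to 396 with sets of an absolute loop sum over 1 left out, a filter chosen after seeing the data. Without the set block, a fit that counts each pool more than once, it rose to 955. Among control spots, not fitted, median S minus C of Cab, NAC1, PRKase and RUBISCO was below 0 in 4 of 4 sets. The means were -0.095, -0.150, -0.126 and -0.153. In R minus C the means were -0.012, -0.068, -0.039 and -0.092, with both signs among the sets for each kind. ChickenGenomic averaged 0.13 in S minus C, with both signs among the sets. Whether this offset bears on the counts was not tested. Unchallenged birds were held in a separate isolator, so that challenge and isolator cannot be told apart in any comparison with C.

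**Figure D1:**
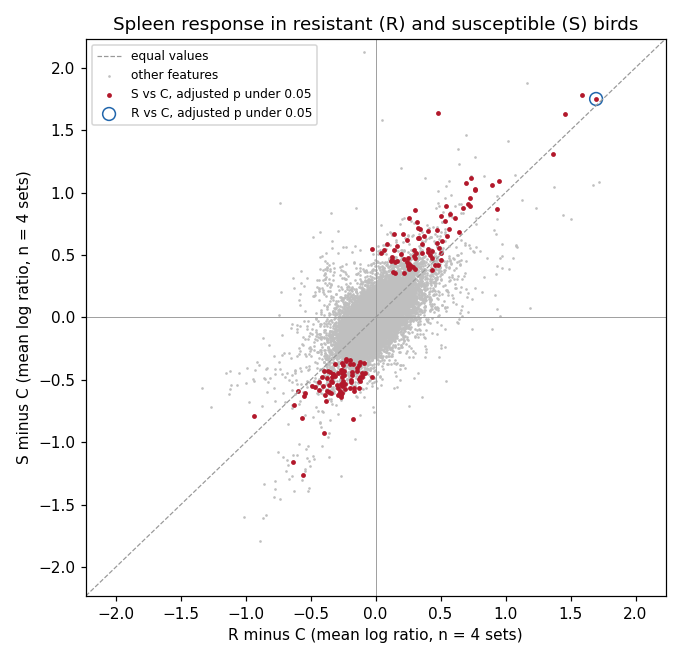
Mean log ratio of S minus C (vertical axis) against R minus C (horizontal axis) for each of 15609 features, n = 4 sets. Red points are the 164 features called in S against C and the blue ring is C0004112_O12, the 1 feature called in R against C. The 164 were chosen on S minus C, and both comparisons share the C pools, so that a place on the same side of 0 (163 of the 164) and a larger S minus C are favoured by the choice.

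The comparison of R with C asked the same of resistant birds. In resistant spleens 1 feature, C0004112_O12, was higher than in unchallenged spleens, by 1.70 ± 0.35 (SD, n = 4; 3.24-fold on base 2; adjusted p = 0.0109, limma). This feature was also among the largest rises in susceptible spleens, and its R minus S value was -0.05 ± 0.30 (SD, n = 4). C0004117_P2 had an R minus C value of 1.59 ± 0.62 (SD, n = 4) and an adjusted p of 0.0936. The falling features of susceptible spleens, Pat_4A3 and Pat_4A1, had R minus C values of -0.56 ± 0.54 and -0.64 ± 0.59 (SD, n = 4), with adjusted p of 0.335 and 0.311. Set 4 carried much of both values (-1.34 and -1.45), and without it they averaged -0.30 and -0.36. At unadjusted p under 0.05 there were 1901 features, and 20.2% of features had the same sign in 4 of 4 sets. The call of C0004112_O12 ended without set 2 (adjusted p = 0.225), without set 4 (0.209), with the direct arrays alone (0.559), with the spread of this comparison alone (0.186) and with the share of males as a covariate and S3 and C3 as males (0.0843), while its log ratio stayed between 1.53 and 1.80 over all alternatives run. Without set 3, 16 features were called, with sets of an absolute loop sum over 1 left out 39, and without the set block 161.

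With R and S averaged (infected against C), 74 features were higher and 40 lower in spleens of challenged than of unchallenged birds. Their median size was 0.48 log units (range 0.29 to 1.72), and C0004112_O12 led them at 1.72 ± 0.32 (SD, n = 4; adjusted p = 0.00267, limma). Of these 114 features, 79 were also called in S against C and 35 were not. The 74 higher features had medians of 0.50 for R minus C and 0.52 for S minus C. The 40 lower features had medians of -0.38 for R minus C and -0.54 for S minus C. The count fell to between 0 and 10 when a set was left out, to 39 with each plate centred, to 2 or 1 with the share of males as a covariate and to 0 with the spread of this comparison alone. It rose to 252 with sets of an absolute loop sum over 1 left out and to 769 without the set block.

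Features chosen on S against C differed from C in the same direction in resistant birds, on average, in sets not used for the choice. The 200 features with the strongest S minus C in 3 sets had an R minus C of 0.27 ± 0.10 (SD, n = 4 sets) in the set left out, signed by the chosen direction. It shares no pool with the choice and would be near 0 with no difference between R and C. Challenge and the separate isolator of C cannot be told apart here either. The left-out R minus C was above 0 in 4 of 4 sets (exact two-sided sign-flip p = 0.125, the smallest that 4 sets allow), 80.0% ± 9.7 of the features had the chosen sign, and S minus C in the same features was 0.45 ± 0.16. The 4 values are not independent, since each set also helped to choose the features of the others. The called features themselves cannot test this shared direction, because both comparisons share the C pools and the features were chosen for a large S minus C. Of the 82 features higher in S against C, 81 had an R minus C value above 0, with medians of 0.58 for S minus C and 0.36 for R minus C. Of the 82 lower features, all 82 had an R minus C value below 0, with medians of -0.51 and -0.26. R minus C was the smaller of the 2 values for 76 of the higher and 80 of the lower features, an order that the choice favours. Across features, R minus C and S minus C correlated at r = 0.643 (Spearman's rho 0.605), against 0.502 in simulations with shared controls and no effect, and their covariance was 0.0256 against a simulated 0.00855. With R minus C from 2 sets and S minus C from the other 2, so that no pool was shared and each mean rested on 2 sets in place of 4, r averaged 0.226 (0.115 to 0.299 over 6 choices). On the same choices of sets R minus C correlated with itself at 0.227 and S minus C with itself at 0.366. Features are not independent replicates, and no p was computed for these correlations.

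The size of the response was compared in 2 ways that avoid choosing features on the values measured. Among 200 features chosen on infected against C in 3 sets, the set left out gave 0.42 ± 0.16 for S minus C and 0.32 ± 0.09 for R minus C (SD, n = 4 sets), signed by the chosen direction. S minus C was the larger in 3 of 4 sets, by 0.10 ± 0.11 on average, which did not pass an exact two-sided sign-flip test (p = 0.25, where 4 sets allow no p below 0.125). These 4 values are not independent either, since each set helped to choose the features of the others. Set 1 gave 0.25, and the other 3 sets averaged 0.05. Across all features, the covariance of S minus C between 2 different sets averaged 0.0233 and that of R minus C 0.0122. S minus C had the higher covariance in 6 of 6 pairs of sets, and the mean of Spearman's rho was 0.269 for S minus C and 0.140 for R minus C. Pairs of sets overlap, and this difference was not tested.

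**Figure D2:**
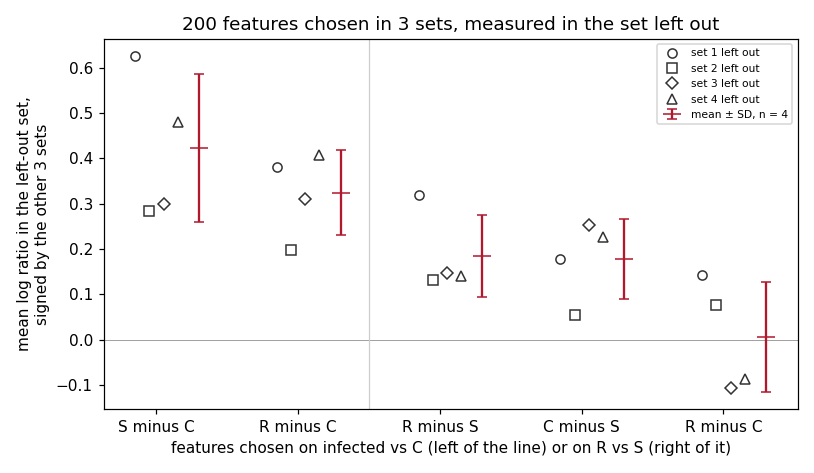
Mean log ratio in the left-out set (vertical axis, log units) of 200 features chosen in the other 3 sets, signed by their direction there. Symbols are the 4 sets and bars the mean ± SD. Left of the line, features chosen on infected against C averaged 0.42 in S minus C and 0.32 in R minus C. Right of it, features chosen on R against S averaged 0.18 in R minus S, of which C minus S made 0.18 and R minus C 0.01.

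The comparison of R with S asked which spleen transcripts go with a low viral load in the bursa. No feature was called between resistant and susceptible spleens: limma gave 0 features past adjusted p 0.05 and 0 past 0.10, with a smallest adjusted p of 0.180, and 1571 at unadjusted p under 0.05 where 780.45 would arise with no effect. The smallest p belonged to C0004105_J6 and Pat-17_d3. C0004105_J6 had an R minus S value of 1.11 ± 0.36 (SD, n = 4; 2.16-fold on base 2; adjusted p = 0.180), with 1.19 ± 0.36 for R minus C and 0.08 ± 0.21 for S minus C. Pat-17_d3 had an R minus S value of 0.99 ± 0.24 (SD, n = 4; 1.98-fold on base 2; adjusted p = 0.180), with 0.90 ± 0.39 for R minus C and -0.09 ± 0.18 for S minus C. Without the set block 7 features were called, C0004105_J6 and Pat-17_d3 among them (adjusted p = 0.0114). The lack of a call with 4 pools a group does not exclude differences as large as those of C0004105_J6 and Pat-17_d3.

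**Figure D3:**
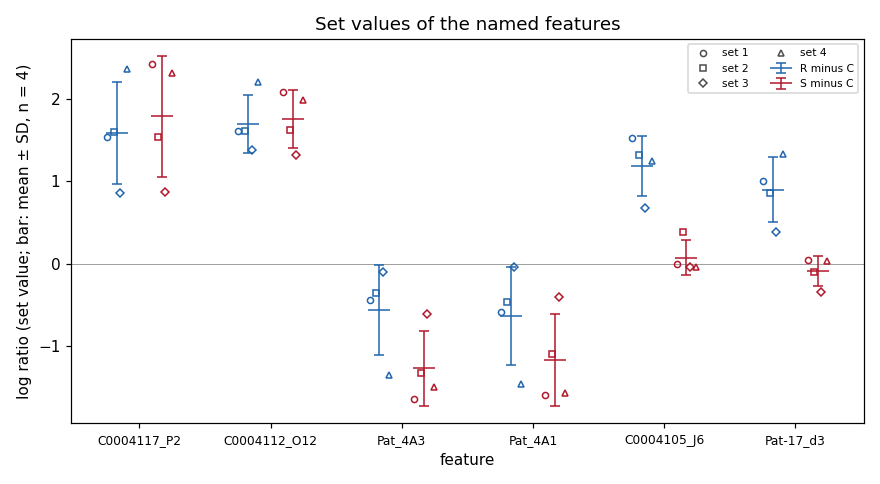
Log ratio (vertical axis) of R minus C in blue and S minus C in red for the 6 named features (horizontal axis), with a symbol for each set and bars for the mean ± SD, n = 4. The first 4 features had the same sign in R minus C and S minus C in every set. C0004105_J6 and Pat-17_d3 lay between 0.38 and 1.52 in R minus C and between -0.35 and 0.39 in S minus C.

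Features chosen on R against S kept their direction, on average, in the sets left out. The 200 features with the strongest R minus S in 3 sets gave 0.18 ± 0.09 (SD, n = 4 sets) in the set left out, in the chosen direction in 4 of 4 sets (exact two-sided sign-flip p = 0.125, the smallest that 4 sets allow), and 70.9% ± 5.5 of them kept their sign. Here too the values of the 4 sets are not independent. Within the 200 features, C minus S was 0.18 ± 0.09 and above 0 in 4 of 4 sets, and R minus C was 0.01 ± 0.12 and above 0 in 2 of 4 sets (SD, n = 4), a contrast that was not tested.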

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

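The tests of left-out sets, plates and clone families were chosen after the patterns had been seen, and the test on pairs of sets without set 1 after its result. In 38 groups of 4 set values, 4 held a value far from the other 3, where chance gives about 1 in 20. In C0004117_P2, the R minus S value of set 1 was -0.89, against -0.01 to 0.07 in the other sets. In C0004105_J6, the S minus C value of set 2 was 0.39, against -0.04 to -0.00398. In the left-out R minus S of 200 chosen features, set 1 gave 0.32, against 0.13 to 0.15. Pools R1 and S1 were single birds, and whether this bears on the values of set 1 was not tested. The median R minus C of the 378 features of the DKFZ426 clone family was 0.10 in set 4, against -0.00628 to -0.00191.

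S against C had 164 called features and R against C had 1, and the R against S test did not separate the groups for any feature. Plate offsets are argued against as the whole cause, since 132 features were called in S against C with each plate centred and 1 in R against C. An unequal share of males stays open. With it as a covariate, S against C had 1 called feature (S3 and C3 as females) or 0 (as males), and R against C also 1 or 0. At unadjusted p under 0.05 there were then 2438 or 2446 features in S against C and 1854 or 1251 in R against C. Noise in set 1, the noisiest set by the loop sum and the set with single-bird pools R1 and S1, was not decided by calls. Without set 1, 0 features were called in S against C and 1 in R against C. S against C also had 0 without set 2 and 0 without set 4. At unadjusted p under 0.05 there were 2115 and 1331 features without set 1 (2827 and 1901 with all sets). In the 3 pairs of sets without set 1 the covariance of S minus C averaged 0.0182 (0.01172 to 0.0257) and that of R minus C 0.00848 (0.00207 to 0.01169), higher for S minus C in 3 of 3 pairs, which goes against this noise as the whole cause but by a margin between the ranges smaller than their spread, so that it stays open. A larger response in susceptible birds remains a hypothesis: S minus C exceeded R minus C in left-out sets by 0.0984 ± 0.108 (SD, n = 4), in 3 of 4 sets, but by 0.0492 averaged over the 3 sets other than set 1, so that it is not separated from chance here, and the viral load, by which the groups were made, stays open as an untested explanation.

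R against S had 1571 features at unadjusted p under 0.05, where 780.45 would arise on average with no effect. Features share the same pools, so that the count varies between splits. With R and S labels exchanged within sets it was 402 to 1034, and 8 splits are too few to exclude chance. An unequal share of males is argued against as the whole cause. At least 1385 features were at unadjusted p under 0.05 with the share of males as a covariate, under both readings of the pools with conflicting labels. Plate offsets are argued against by 1578 features with each plate centred. An R against S difference shared by the sets is a candidate explanation, as the left-out value of 0.185 had the chosen direction in 4 of 4 sets. Those 4 values are not independent, since each set also helps to choose the features of the others. The submitters sorted R from S birds by viral load, so that a difference in the stage of infection and a difference between the birds cannot be separated by this test.

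Features of the DT40subNB clone family were called higher in S against C more often than others, 18 of 1798 against 64 of 13811 (odds ratio 2.17, Fisher's exact adjusted p = 0.0317 over 8 tests), and lower less often, 3 of 1798 (odds ratio 0.291, adjusted p = 0.0452). Fisher's test takes features as independent, though all were measured in the same pools, so that its p-values may be too small. With each plate centred the odds ratio of lower features was 0.442 and no longer passed (Fisher's exact p = 0.204), and that of higher features was 1.87 (95% interval 0.983 to 3.33, Fisher's exact p = 0.0459), so that plate offsets cannot be told apart from a property of these clones. Limma's camera test gave the family's S minus C an adjusted p of 0.00451, and an adjusted p of 0.287 with an estimated correlation. What the clones of this family are is not given in the sources used here, and no biological explanation was tested.

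Chance assignment of pools was tested by exchanging labels within sets. For infected against C, 1 of 81 choices of 1 pool per set as the control, the real one, gave as many features (114, with 0 as the highest of the others). This argues against chance assignment of the pools to the groups at that level. It does not single out C, since most of the choices mix R, S and C pools. At unadjusted p under 0.05 the separation was smaller, 2705 features against 2329 with the 4 S pools as the control, the highest of the others, and 2247 with R2 in place of C2. For the comparisons of 2 groups, 8 splits are too few for a share under 0.05. The real value and the highest of the others were 164 and 0 for S against C, reached by 1 split, 1 and 0 for R against C, reached by 1 split, and 0 and 0 for R against S, reached by 8. In that order they were 2827 and 1416, 1901 and 1113, and 1571 and 1034 at unadjusted p under 0.05.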

How the results depend on the processing

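Plate centring, the loop-sum limit, robust eBayes and the left-out and clone-family tests were chosen after seeing the data. The cause of a change was not tested unless given. R against S stayed at 0 features (1066 to 1681 at unadjusted p under 0.05) in limma under every alternative run except without a replicate block, where 7 were called. That fit took the 12 arrays as independent ratios, counted each pool more than once by its construction, and called 161 in R against C, 955 in S against C and 769 in infected against C. The direct arrays alone gave 0 in R against C and 0 in S against C. The spread of 1 comparison alone gave 0 in R against C, 1 in S against C and 0 in infected against C. The share of males as a covariate gave 1 (S3 and C3 as females) and 0 (as males) in S against C, 2 and 1 in infected against C, and 1 and 0 in R against C. Scale normalization raised S against C to 288. Leaving out a set gave 0 to 16 in R against C, 0 to 3 in S against C and 0 to 10 in infected against C. Simulated arrays with 3 sets still gave 114 to 144 calls in S against C, with 94% to 97% of changes of 1 log unit and 12% to 37% of changes of 0.5 recovered. Those simulated changes differ in size from the real ones and their noise is independent between features, and the cause of the fall was not tested. Sets with an absolute loop sum over 1 left out gave 39 in R against C, 396 in S against C and 252 in infected against C, over 14984 features. Plate centring lowered infected against C to 39. At adjusted p under 0.10 there were 48, 709 and 429. The correlation of R minus C with S minus C was 0.581 to 0.662 with a set left out and 0.226 over sets that share no pool, where each mean also rests on fewer sets, and where R minus C correlated with itself at 0.227 and S minus C with itself at 0.366.

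Of 117 values of named features and clone families under alternatives, 76 kept their direction and side of the threshold, 39 fell short of it in the same direction, 2 passed it, and 0 turned. The 76 include 14 of 15 alternatives each for C0004105_J6 and Pat-17_d3, which were not called and stayed so. In S against C, C0004117_P2 kept its call in 7 of 15, C0004112_O12 in 9, Pat_4A3 in 7 and Pat_4A1 in 6. C0004112_O12 kept its call in R against C in 10 of 15. Clone families were not counted with a set left out, where too few features were called. The 2 that passed were C0004105_J6 and Pat-17_d3 without the block (adjusted p = 0.0114, over a range of 0.0114 to 0.715). Pat_4A1 also fell short with each plate centred (adjusted p = 0.0514, range 0.0067 to 0.237). The odds ratio of higher features in the Pat family went from 1.94 to 1.15 with each plate centred, and that of the C family from 0.419 to 0.672, and neither passed there (Fisher's exact p = 0.609 and 0.12). Gene-level counts, gene lists and filters on missing values were not run, the first for want of gene names and the last because no value is missing. Signal over background was not analysed here, and the number of arrays limits the precision.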

Other observations

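All tests in this part were chosen after seeing the data. The clone families differed in how often they were called in S against C. Fisher's tests below take features as independent, though all share the same pools. They also overlap, since each family is set against all the others. The C family (11447 features) held 44 higher features, 0.384% of it, against 0.913% of the others (odds ratio 0.419, Fisher's exact adjusted p = 0.00108 over 8 tests), and 63 lower features. The Pat family (1983 features) held 18 higher and 15 lower features (odds ratio of higher features 1.94, Fisher's exact adjusted p = 0.0452). With each plate centred neither odds ratio passed (0.672 in the C family, Fisher's exact p = 0.12, and 1.15 in the Pat family, p = 0.609). Limma's camera test of S minus C gave the Pat family an adjusted p of 0.0413, and an adjusted p of 0.588 with an estimated correlation, and the C family 0.00451 and 0.0385. The DKFZ426 family (378 features) held 2 higher and 1 lower. Family medians of S minus C were small, from -0.02 in the C family to 0.04 in the DT40subNB family, beside SDs of 0.02 to 0.05 over the 4 sets. With the arrays median-centred or scaled, the odds ratios of higher features were 0.39 and 0.333 in the C family, 2.07 and 2.28 in the Pat family, and 2.32 and 2.64 in the DT40subNB family.

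The overall sign of the ratios was looked for in the labelled sex of the pools. In the 3 sets with undisputed labels, 70 features followed the share of males by over 0.2 log units in every set and 37 ran against it. Of 108 ways to assign an odd pool and its direction to these sets, 3 were as one-sided, and the median assignment held 155 such features, more than the 107 found, so that the sign was not settled.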
